A study of Homo sapiens with 15 samples.

How the data were processed

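RNA from H1 human embryonic stem cells was profiled in 15 samples, 5 groups of 3, with 1 array per sample. The groups were set from the treatment type and treatment length in the labels. Per the labels' protocols, total RNA was extracted with Trizol, treated with DNase and cleaned on a column, and biotin-labelled cRNA was made with an Illumina amplification kit. BeadStudio is named in the submitters' processing notes, with no version given in the sources used here. The deposited tables, 1 per chip, hold linear probe intensities normalized by the authors, per the file headers and names, while the normalization method and background setting are not given in the sources used here. Beside each intensity they hold a detection p-value, which the authors deposited as the software writes it. The authors' series matrix holds the same intensities (largest difference 0) for 29285 of the 29377 probes.

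No deposited intensity was below 16, and the lowest per array lay between 40.6 and 58, so background had not been subtracted to 0 and fold differences of dim genes are understated. The 75th percentiles of the 2 chips did not overlap, so joint normalization of the chips was not shown. The intensities of all 15 arrays were therefore quantile normalized together, the branch laid down for this case. The planned floor of 16 changed nothing, and log2 was taken. Tests were made only within a chip, and the planned tests of EV 48 h against 0 h, EV 96 h against 48 h and CCNB1 96 h against 48 h, with the gene sets drawn from the first of these, were not run.

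Probes were kept where the detection p was below 0.01 in all 3 arrays of at least 1 group, which left 15393 probes, 14757 of them with a gene symbol. Of all probes, 27988 had 1 gene symbol, 0 several and 1389 none in the platform annotation. Symbols were updated through Entrez IDs for 27819 probes with the gene table of the GRCh38.p14 assembly, used for names only, and no coordinates are given because no build is named. A gene was represented by its kept probe with the highest mean log2 intensity, giving 11390 genes, of which 2753 had more than 1 kept probe. Of the 112 other probes of the named genes, counted per comparison, 104 had the same sign and 96 also passed the threshold in that direction. The sizes could differ widely between probes, so folds hold for the probe used. Probe sequences were not used here, so probes of POU5F1, LEFTY1 and LEFTY2, HSPA1A and HSPA1B, CRIPTO, MT1H and the histone genes may also bind near-identical copies, and their values are uncertain to that extent.

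Group means were fitted over all 15 arrays with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a variance trend, 10 residual degrees of freedom), and genes were called at a Benjamini-Hochberg adjusted p below 0.05, two-sided. Replicate numbers are given in the labels without saying what they share. Between EV 96 h and CCNB1 96 h the deviations of same-numbered samples from their group means correlated with r of 0.113, 0.309 and 0.367. No other pair of groups had all 3 above 0.1. Values of similar size but mixed sign occurred elsewhere, with -0.217, 0.249 and -0.322 between EV 0 h and CCNB1 96 h. Samples with unlike numbers were not compared, so a pairing at 96 h is possible but not settled. The main fit was unpaired, and replicate blocks were fitted only as alternatives. The median SE of a within-time difference was 0.093 on the log2 scale. A gene not detected in any of the 3 arrays of a group (detection p of 0.01 or more) has only a bound there. Its fold is given as at least the bright group's mean over the mean, per array, of the higher of the lowest detected signal and the gene's own signal, and no fold is given where both groups were undetected or the bound was under 1. Unless stated otherwise, all 3 arrays of one group lay beyond all 3 of the other for each named gene, with HSPA4L and KLF5 at 48 h as exceptions, and CCNB1 between EV 96 h and 0 h, which did not change. Signed differences are CCNB1-labelled minus EV, or 96 h minus 0 h.

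The rule for naming genes, the 26 gene lists, the normalization branches and the settings varied were written before the data were examined. The rule took the 8 genes with the largest increase and the 8 with the largest decrease per comparison among called genes with separated groups and an official symbol (5 and 5 for the change of the CCNB1 difference), up to 4 called members of each list that was called or had 3 or more called members, and CCNB1, POU5F1, NANOG, SOX2, LEFTY1, LEFTY2 and NODAL everywhere. Members behind a count of 5 or fewer in a list were named after their values were seen.

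The gene lists covered the pluripotency network, naive-state markers, Nodal targets, TGF-beta and activin components, FGF/ERK, BMP and WNT targets, neuroectoderm, neural crest, mesendoderm, endoderm, trophectoderm and amnion, mesoderm and mesenchyme, and fibroblast and matrix genes. The others were G2 and mitosis, G1/S and replication, p53 target, interferon, NF-kappaB, stress and amino acid response, heat shock, hypoxia and glycolysis, cholesterol and fatty acid synthesis, histone, ribosomal protein and reference genes. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 26 lists per comparison, again with an estimated correlation, and with fry, which tests whether a list's genes move one way on balance and does not compare them with other genes. Some genes stood in 2 lists, such as SMAD7, TFAP2A, SESN2 and CRIPTO.

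Relations between comparisons were computed as Pearson's and Spearman's correlations and slopes across genes, with 100 simulations of unchanged groups where arrays were shared. The steps were tested on simulated data with 200 of 11390 genes changed. At 1.25-fold, 58.2% of changed genes were recovered for CCNB1 against EV at 48 h, 43.3% at 96 h, 40.3% for EV 96 h against 0 h and 5.97% for the change of the CCNB1 difference. At 1.5-fold these shares were 100%, 100%, 100% and 85.1%, and at 2-fold 100% in each. There were 4, 11, 8 and 6 false calls. In the data 25.7 to 59.0% of genes were called, so the adjusted threshold was looser there and these shares do not carry over. In a simulated shift of the p53 list it was found, and 1 of the other lists was called. Noise was simulated independently for each gene, so the list tests were not checked under inter-gene correlation.

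The fits were repeated with other floors (8 and 64), an offset of 50, and no detection filter or one at 0.05. They were also repeated with median scaling, the series matrix, a replicate block, fits on the compared groups only and no variance trend. Other settings were array weights, every probe tested, a 1.5-fold limit and each array left out. The deposited values without quantile normalization, quantile normalization within each chip, background correction from the detection p-values (limma's nec, offset 16) and a replicate block for the 96 h samples alone were 4 further settings added after seeing the data. The deposited scanner metrics were not used because nothing pairs their entries with samples. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.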

Results

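Transcript levels were measured in H1 cells, an established human embryonic stem cell line, on Illumina bead arrays carrying 29377 probes. Cells had been infected with an empty lentiviral vector (EV) or, per the labels, with a vector overexpressing CCNB1, the cyclin that activates CDK1 at entry into mitosis. The cells were kept in mTeSR1 lacking select factors, given in the series design as bFGF and TGF-beta, which maintain these cells undifferentiated. The 15 arrays formed 5 groups of 3, namely EV at 0, 48 and 96 h and CCNB1 at 48 and 96 h. The titles of the EV 0 h samples give 24 h where their treatment length is labelled 0 h, and they are called EV 0 h here. The series title states the question as how the cell cycle restricts the exit from pluripotency.

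Each array detected between 13897 and 15679 probes at a detection p below 0.01, or 47.3 to 53.4% of all probes, with a median deposited intensity of 97.9 to 106.7. The number of arrays limits the precision, and the labels do not say whether replicates were separate cultures, so all p-values measure only the spread between these samples, which may be technical. Within groups, log2 intensities of 2 arrays correlated with r between 0.988 and 0.997 across the 11390 genes tested, which leaves out probes that were not kept. CCNB1 96 h replicate 3 lay farthest from its group, with an SD of log2 differences of 0.219 and 0.263 from the other 2 arrays, where other pairs of arrays within a group gave 0.132 to 0.179. The EV 48 h and CCNB1 48 h samples were on 1 chip and the other 3 groups on another, with 75th percentiles of deposited intensity of 308.6 to 313.7 and 320.6 to 331.7. Vector comparisons at each time and EV 96 h against EV 0 h stayed within a chip and were tested, while comparisons of 48 h with 0 or 96 h crossed chips and are given as levels without a test.

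The single CCNB1 probe did not show higher signal in all samples labelled as overexpressing CCNB1. At 48 h its intensity was 1702 ± 102 in the CCNB1-labelled samples and 2009.7 ± 106 in EV samples (mean ± SD, n = 3 each), a log2 difference of -0.24 ± 0.085 (SE, adjusted p = 0.036), against the direction of the label. At 96 h it was 2028 ± 89.5 and 1628 ± 127, a log2 difference of 0.32 ± 0.085 (adjusted p = 0.0034). EV samples differed by 0.029 ± 0.085 between 96 h and 0 h (adjusted p = 0.79). The 48 h call was lost in 7 alternatives, with adjusted p up to 0.151 on leaving out EV 48 h replicate 3 (0.143 without CCNB1 48 h replicate 3, 0.0772 without EV 48 h replicate 2, 0.0605 without CCNB1 48 h replicate 1), 0.0985 with median scaling, 0.064 on the deposited values and 0.0589 without the detection filter. Whether the probe lies in the part of the transcript carried by the vector is not given in the sources used here, so it may not report the transgene, and the samples are called CCNB1-labelled throughout. Every direction below rests on the labels for this reason.

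**Figure D1:**
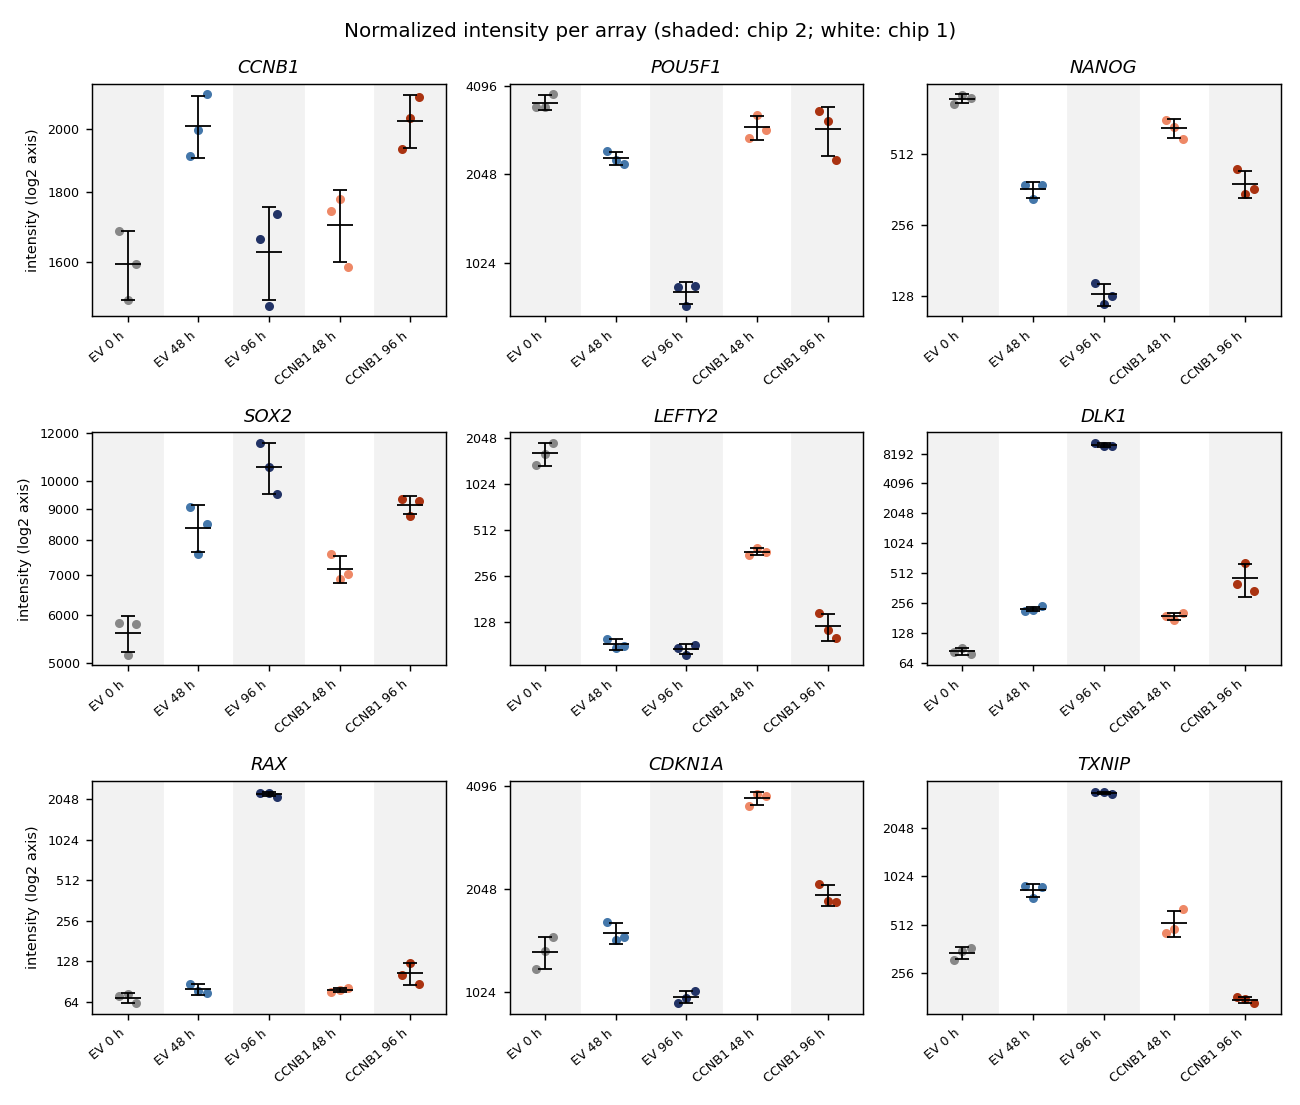
Normalized intensity (log2 axis) of 9 genes in each array of the 5 groups, with group means and SD as black bars (n = 3) and chip 2 groups shaded. POU5F1 averaged 2915 in CCNB1 96 h and 815 in EV 96 h, and DLK1 462 and 9990.4.

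To describe the course under the control vector, EV 96 h was compared with EV 0 h. Time since infection, time in culture and time without the factors cannot be told apart in this comparison. Pluripotency factors fell: POU5F1 (OCT4) was 4.41-fold lower at 96 h, with intensities of 815 ± 70.1 against 3588 ± 208, and the homeobox factor NANOG was 6.75-fold lower. Genes of the Nodal pathway also fell, LEFTY2 at least 16.8-fold, LEFTY1 at least 6.83-fold, the ligand NODAL at least 3.63-fold and the Nodal co-receptor CRIPTO (TDGF1) 11.9-fold. Forebrain and eye-field genes rose, among them RAX (at least 22.2-fold), LHX2 (at least 12.3-fold) and SIX3 (at least 3.58 on the log2 scale), and DLK1, which encodes a Notch-ligand-like membrane protein, rose from below detection to 9990.4 ± 407 (at least 99.4-fold). SOX2, expressed in both pluripotent and neural progenitor cells, was 1.88-fold higher (log2 difference 0.91 ± 0.082, adjusted p = 1.0e-09).

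Over 11390 genes, 6720 differed between EV 96 h and EV 0 h (limma, adjusted p below 0.05). Of these, 3340 were higher and 3380 lower, with 494 and 331 changed at least 2-fold. Median scaling gave 3737 higher and 2856 lower. The largest increases besides DLK1 and RAX included that of FRZB, a secreted WNT antagonist (39.7-fold, log2 difference 5.31 ± 0.087, adjusted p = 1.0e-23). The others were those of VWF (at least 28.0-fold), the ephrin receptor EPHA4 (31.8-fold), DLX5 (at least 24.1-fold), LMO1 (at least 20.6-fold) and PAMR1 (30.4-fold). PAMR1's other probe, near background, differed by 0.57 on the log2 scale, against 4.93 for the probe used. The largest decreases besides LEFTY2 were those of the peptide precursor NTS (19.6-fold, log2 difference -4.30 ± 0.11, adjusted p = 1.2e-20), ANXA1 (at least 17.2-fold), SPP1 (17.4-fold), CFAP95 (15.5-fold), the smooth muscle actin ACTG2 (14.6-fold), AFP (at least 12.1-fold) and the metallothionein MT1H (13.7-fold).

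By gene list, 13 of 19 measured neuroectoderm markers rose and 3 (SOX3, NES and TUBB3) fell, the same counts when adjusted over the list alone, with a median log2 change of 1.46 (camera adjusted p = 2.6e-05), or 1.36 with members below detection at their bounds and 0.37 without the detection filter. Of 26 pluripotency genes, 18 fell and 6 rose (19 and 6 adjusted over the list alone), with a median of -0.62 (adjusted p = 0.00035), or -0.98 after background correction. The riser with the largest change in that list was HESX1 (23.8-fold), which is also a forebrain factor. Among 10 Nodal target genes 7 fell and 1, TGIF2, rose (7 and 2 adjusted over the list alone), with a median of -0.78 (adjusted p = 0.0015), or -1.40 after background correction. Cholesterol and fatty acid synthesis genes moved together, 16 of 19 falling and none rising, the same counts when adjusted over the list alone (median -0.62, adjusted p = 2.6e-05), led by MVD (2.64-fold) and IDI1 (2.17-fold). Of the 13 heat shock genes 12 fell, also when adjusted over the list alone (median -0.65, adjusted p = 0.00015), HSPA1B by 2.53-fold and HSPA8 by 2.29-fold. These 5 lists held their calls with an estimated correlation.

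A further 5 lists passed only with the preset correlation. Among endoplasmic reticulum stress and amino acid response genes, 12 of 18 rose and 3 (SDF2L1, HSPA5 and ATF4) fell, also when adjusted over the list alone (median 0.83, adjusted p = 0.0036, and adjusted p = 0.36 with an estimated correlation). The stress-induced DDIT4 and DDIT3 (CHOP) rose 9.33-fold and 5.31-fold, whereas SDF2L1 and HSPA5 encode chaperones of the endoplasmic reticulum. BMP target genes had 6 of 10 members higher and 1 (BAMBI) lower, also when adjusted over the list alone (median 1.23, or 1.02 with members at their bounds, adjusted p = 0.0076, and adjusted p = 0.34 with an estimated correlation), ID4 rising 9.76-fold and ID2 5.54-fold. Neural crest markers had 6 of 9 higher and 1 (ETS1) lower, also when adjusted over the list alone (median 0.77, adjusted p = 0.0042, and adjusted p = 0.052 with an estimated correlation), with TFAP2A up at least 14.1-fold. Trophectoderm and amnion markers had 7 of 9 higher and 1 (KRT18) lower, also when adjusted over the list alone (median 0.46, or 0.19 with members at their bounds, adjusted p = 0.015, and adjusted p = 0.36 with an estimated correlation). FGF/ERK target genes had 10 of 16 lower and 4 (EGR1, CCND1, SPRY1 and SPRY2) higher, also when adjusted over the list alone (median -0.60, adjusted p = 0.0099, and adjusted p = 0.18 with an estimated correlation), MYC falling 3.32-fold and the ERK phosphatase gene DUSP6 3.03-fold. Without the detection filter the medians were 0.63 for BMP targets, 0.13 for neural crest and 0.23 for trophectoderm markers, the last 0.28 with an offset of 50, and after background correction 1.40 and 0.71 for these 2 marker lists.

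CCNB1-labelled and EV samples were then compared at 48 h. The secreted phosphoprotein gene SPP1 was 10.7-fold higher in CCNB1-labelled samples (2415 ± 235 against 226 ± 32.6), the neurotensin gene NTS 7.98-fold and ANXA1 6.88-fold. Nodal pathway genes were higher, LEFTY2 at least 3.56-fold, LEFTY1 at least 2.08-fold and NODAL at least 2.14-fold, with all 3 EV 48 h arrays below detection for each. NANOG was 1.81-fold higher (658 ± 59.9 against 363 ± 27.8). Lower in CCNB1-labelled samples were INHBE (5.29-fold), the iroquois homeobox gene IRX3 (4.36-fold), LMO1 (at least 3.75-fold) and CYP26A1, a retinoic acid hydroxylase (3.36-fold).

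In all, 3200 of 11390 genes differed at 48 h, 1464 higher and 1736 lower in CCNB1-labelled samples (1631 and 1488 under median scaling), with 100 and 55 changed at least 2-fold. Other leading increases were those of CYTOR (6.38-fold), the caveolin gene CAV1 (5.78-fold), GLIPR1L1 (at least 4.83-fold) and AK4 (4.26-fold). The skeletal actin ACTA1 was also among them (4.41-fold, log2 difference 2.14 ± 0.098, adjusted p = 4.2e-14). The other probes of CYTOR differed by 1.10 and 1.02 on the log2 scale, against 2.67 for the probe used. That of CAV1 differed by 1.07, against 2.53. Other leading decreases were those of DDIT4 (4.26-fold, log2 difference -2.09 ± 0.16, adjusted p = 2.0e-10), FILIP1 (3.65-fold), CHAC1 (3.27-fold, detected in 1 of 3 CCNB1 48 h arrays) and TFAP2A (4.01-fold, detected in 2 of 3). POU5F1 was 1.27-fold higher (log2 difference 0.34 ± 0.11, adjusted p = 0.022). That call was lost on leaving out CCNB1 48 h replicate 2 (adjusted p = 0.123), EV 48 h replicate 3 (0.0845) or EV 48 h replicate 2 (0.0606). Its other probe, near background, differed by 0.14 (adjusted p = 0.24). SOX2 differed by -0.23 ± 0.082 (adjusted p = 0.042). This call was lost in 9 alternatives with adjusted p up to 0.289 under median scaling and 0.196 without EV 48 h replicate 1. Its other probe differed by -0.53 (adjusted p = 0.00027).

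p53 target genes gave the lowest list p at 48 h. Of 23 measured, 18 rose and 1 (SESN2) fell (20 and 1 adjusted over the list alone), with a median log2 difference of 0.54 (camera adjusted p = 5.9e-12). CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, was 2.47-fold higher, with 3761 ± 170.4 against 1526 ± 105, PHLDA3 2.09-fold, and GDF15 2.58-fold with EV 48 h detected in 1 of 3 arrays. FGF/ERK target genes had 12 of 16 members higher and 2 (EGR1 and CCND1) lower (14 and 2 adjusted over the list alone), with a median of 0.51 (adjusted p = 6.4e-09), DUSP6 with a log2 difference of 2.00 and the ETS factor ETV5 at 2.94-fold. Nodal target genes had 7 of 10 higher and 1 (TGIF2) lower, also when adjusted over the list alone (median 0.66, adjusted p = 9.2e-06). Fibroblast and extracellular matrix genes had 9 of 12 higher and 1 (COL5A1) lower (10 and 1 adjusted over the list alone), with a median of 0.39 (adjusted p = 1.6e-06). Its leading members were the actin-binding TAGLN (3.97-fold), the smooth muscle actin ACTA2 (3.06-fold) and the collagen COL5A2 (2.72-fold). These 4 lists held with an estimated correlation.

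Stress and amino acid response genes were lower at 48 h, 12 of 18 falling and 1 (SDF2L1) rising, also when adjusted over the list alone (median -0.42, adjusted p = 4.1e-06, and adjusted p = 0.20 with an estimated correlation). Histone genes had 6 of 10 higher and none lower (6 and 1 adjusted over the list alone), with a median of 0.43 (adjusted p = 0.00030, and adjusted p = 0.21 with an estimated correlation). Naive-state markers had 3 of 6 higher, NLRP7, DPPA3 and KLF5, and none lower (4 and 0 adjusted over the list alone), with a median of 0.26, or 0.21 with members at their bounds (adjusted p = 0.025, and adjusted p = 0.20 with an estimated correlation). KLF5, whose arrays overlapped between the groups, lost its own call on leaving out CCNB1 48 h replicate 1 (adjusted p = 0.20), EV 48 h replicate 1 (0.11), CCNB1 48 h replicate 2 (0.065) or EV 48 h replicate 2 (0.064), and DPPA3 on leaving out EV 48 h replicate 1 (0.054). The naive-state call was also lost without CCNB1 48 h replicate 1, without the detection filter (median 0.031) and at a detection limit of 0.05 (0.16), and its median was 0.50 after background correction. The histone median was 0.23 without CCNB1 48 h replicate 3 and 0.68 after background correction. Heat shock genes had 3 of 13 higher, HSPA1B, HSPA1A and HSPA4L, and none lower, also when adjusted over the list alone (median 0.15, adjusted p = 0.040, and adjusted p = 0.20 with an estimated correlation). This call was also lost on leaving out EV 48 h replicate 3, CCNB1 48 h replicate 1 or CCNB1 48 h replicate 3, with a median of 0.22 without EV 48 h replicate 2. Neither pluripotency genes (median 0.11, adjusted p = 0.12) nor neuroectoderm markers (median -0.066, adjusted p = 0.22) passed the list test at 48 h.

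At 96 h the same comparison showed pluripotency genes higher and forebrain genes lower in CCNB1-labelled samples. POU5F1 was 3.54-fold higher (2915 ± 559.5 against 815 ± 70.1), NANOG 2.94-fold, the pluripotency factor PRDM14 3.44-fold and CRIPTO 6.28-fold. DLK1 was 22.5-fold lower (462 ± 166 against 9990.4 ± 407), SIX3 6.32-fold, RAX 21.7-fold with 2 of 3 CCNB1 96 h arrays above detection, and LHX2 13.3-fold with 1 of 3 above detection. TXNIP, which encodes a thioredoxin-binding protein, was 19.7-fold lower (174 ± 8.31 against 3413 ± 44.0).

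Of 11390 genes, 5367 differed at 96 h, 2732 higher and 2635 lower in CCNB1-labelled samples, with 140 and 249 changed at least 2-fold. Median scaling gave 2536 higher and 2756 lower. Other leading increases were those of CFAP95 (11.7-fold, log2 difference 3.55 ± 0.12, adjusted p = 4.4e-17), the proteoglycan gene VCAN (6.94-fold), MT1H (5.47-fold), SYT4 (at least 4.61-fold), VAT1L (4.48-fold), NTS (4.46-fold) and the zinc-finger factor BCL11A (4.41-fold). Other leading decreases were those of INHBE (14.1-fold, log2 difference -3.82 ± 0.16, adjusted p = 4.2e-15), VWF (9.03-fold), the kinase gene MAPK10 (8.68-fold) and RIPPLY3 (7.85-fold). POU5F1's other probe, near background, differed by 0.14 (adjusted p = 0.18). SOX2 differed by -0.20 ± 0.082 (adjusted p = 0.044). This call was lost in 10 alternatives with adjusted p up to 0.445 on the deposited values and 0.242 without EV 96 h replicate 1. Its other probe differed by -0.60 (adjusted p = 2.6e-05). Within the Nodal list, LEFTY2 was at least 1.23-fold higher, whereas LEFTY1 was below detection in all 6 arrays and NODAL above it in 1 array. The list as a whole had a median of 0.32, or 0.00 with members at their bounds (adjusted p = 0.31), and FGF/ERK target genes one of -0.081 (adjusted p = 0.77).

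Of 26 pluripotency genes, 18 rose and 3 (HESX1, SFRP2 and SOX2) fell (18 and 4 adjusted over the list alone), with a median log2 difference of 0.58 (camera adjusted p = 3.0e-06). Neuroectoderm markers had 13 of 19 lower and 3 (TUBB3, NES and SOX3) higher, also when adjusted over the list alone (median -0.67, adjusted p = 9.2e-07), and the median was -0.31 without the detection filter. Heat shock genes had 11 of 13 higher and none lower (12 and 0 adjusted over the list alone), with a median of 0.58, or 0.45 with members at their bounds (adjusted p = 4.6e-05), HSPA8 at 2.19-fold and HSPA1B at 2.24-fold. p53 target genes had 17 of 23 higher and 2 (GADD45A and SESN2) lower (18 and 2 adjusted over the list alone), with a median of 0.36 (adjusted p = 0.00034), or 0.55 after background correction. PHLDA3 was 2.55-fold higher, the apoptosis gene BAX 2.10-fold and CDKN1A 1.98-fold. These 4 lists held with an estimated correlation, in which pluripotency genes had an adjusted p of 0.0051.

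The lowest list p at 96 h was that of stress and amino acid response genes, of which 15 of 18 fell and 2 (SDF2L1 and HSPA5) rose, also when adjusted over the list alone (median -1.23, adjusted p = 3.1e-08, and adjusted p = 0.13 with an estimated correlation). TRIB3 was 6.95-fold lower, DDIT4 6.34-fold, the gluconeogenic enzyme gene PCK2 5.70-fold and DDIT3 5.53-fold. Cholesterol and fatty acid synthesis genes had 11 of 19 higher and 1 (FADS1) lower, also when adjusted over the list alone (median 0.31, adjusted p = 0.0044, and adjusted p = 0.15 with an estimated correlation), HMGCS1 at 1.66-fold. Histone genes had 8 of 10 higher and 1 (H4C3) lower, also when adjusted over the list alone (median 0.56, adjusted p = 0.0091, and adjusted p = 0.37 with an estimated correlation). G1/S and DNA replication genes had 12 of 27 higher and none lower, also when adjusted over the list alone (median 0.21, adjusted p = 0.012, and adjusted p = 0.19 with an estimated correlation), the G1 cyclin CCNE1 at 1.52-fold. BMP target genes had 5 of 10 lower (ID4, ID2, ID3, SMAD6 and MSX2) and 1 (BAMBI) higher, also when adjusted over the list alone (median -0.47, adjusted p = 0.012, and adjusted p = 0.35 with an estimated correlation). Neural crest markers had 6 of 9 lower and 1 (ETS1) higher, also when adjusted over the list alone (median -0.47, adjusted p = 0.030, and adjusted p = 0.15 with an estimated correlation). That call was also lost without CCNB1 96 h replicate 3 (adjusted p = 0.0593) and after background correction (0.059, median -0.77). Without the detection filter the medians were -0.17 for BMP targets and -0.15 for neural crest markers.

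G2 and mitosis genes other than CCNB1 did not pass the list test at 48 h (median log2 difference -0.038, adjusted p = 0.60) or 96 h (0.14, adjusted p = 0.61). At 96 h CDC20 was 1.40-fold higher and CCNB2 1.42-fold lower. Among the lists past the threshold in none of the 4 comparisons tested here, interferon-stimulated genes had medians of 0.077 at 48 h (adjusted p = 0.48, with a mean of -0.003) and -0.12 at 96 h (adjusted p = 0.75), although HERC5 was 3.86-fold higher and BST2 3.09-fold lower at 96 h. At 96 h the medians were 0.074 for TGF-beta and activin pathway components (adjusted p = 0.80, mean -0.030), -0.19 for WNT target genes (adjusted p = 0.91, mean 0.16), -0.22 for endoderm markers (adjusted p = 0.77, mean 0.064) and 0.12 for mesoderm and mesenchyme markers (adjusted p = 0.80, mean -0.009). NF-kappaB target genes had a median of -0.17 (adjusted p = 0.61), reference genes 0.11 (adjusted p = 0.61) and ribosomal protein genes -0.12 (adjusted p = 0.063), the last turning to 0.011 on the deposited values. Single members of these lists nevertheless changed, such as the WNT target AXIN2 (2.73-fold higher), AFP (at least 3.19-fold higher) and the cadherin CDH2 (2.47-fold lower) at 96 h.

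**Figure D2:**
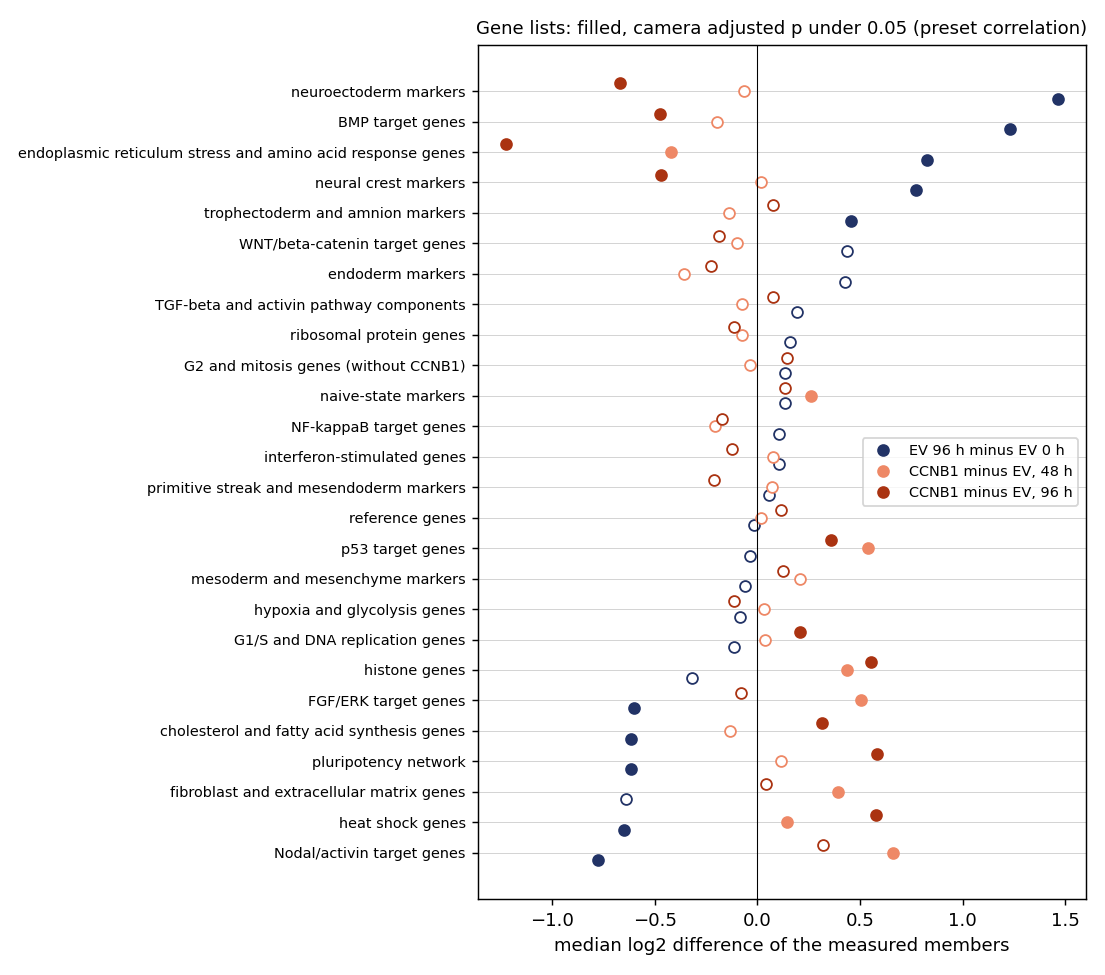
Median log2 difference of the measured members of each of the 26 gene lists (horizontal axis) in 3 comparisons, marked by colour, with filled points where camera's adjusted p with the preset correlation was below 0.05. Neuroectoderm markers lie at 1.46 for EV 96 h minus EV 0 h and at -0.67 for CCNB1 minus EV at 96 h.

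Whether the CCNB1 difference changed between 48 h and 96 h was tested as the difference of the within-chip differences. The POU5F1 difference grew by 1.48 ± 0.16 on the log2 scale (adjusted p = 1.1e-07), though its other probe, near background, showed -0.00025 (adjusted p = 1.00), and the NANOG difference grew by 0.70 ± 0.15 (adjusted p = 0.00095). In the opposite direction the LEFTY2 difference changed by -1.54 ± 0.17 (adjusted p = 2.3e-07), LEFTY1 by -1.05 ± 0.13 and NODAL by -1.05 ± 0.13, with all EV arrays at both times below detection for these 3 genes. CCNB1 itself moved by 0.56 ± 0.12 (adjusted p = 0.0012) and SOX2 by 0.021 ± 0.12 (adjusted p = 0.92). The largest shifts downward were those of RAX (-4.43), DLK1 (-4.24), LHX2 (-3.83), TXNIP (-3.61) and ENC1 (-2.98), and upward those of CFAP95 (2.59), GADD45G (2.54), CACHD1 (2.47), IDO1 (2.37) and PCDH7 (2.36). RAX and LHX2 were below detection in all 6 arrays at 48 h.

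In total 2928 genes changed their CCNB1 difference, 1459 upward and 1469 downward (1126 and 1669 under median scaling). FGF/ERK target genes shifted downward, 9 of 16 falling and 1 (EGR1) rising, also when adjusted over the list alone (median -0.48, camera adjusted p = 3.5e-06), as did neuroectoderm markers with 10 of 19 down and 2 (TUBB3 and OTX2) up (12 and 2 adjusted over the list alone, median -0.35, adjusted p = 2.9e-06). Nodal target genes had 4 of 10 down (LEFTY2, LEFTY1, NODAL and SMAD7) and 1 (PMEPA1) up, also when adjusted over the list alone (median -0.24, adjusted p = 0.0054). Fibroblast genes had 7 of 12 down and 2 (CCN2 and COL1A1) up (8 and 3 adjusted over the list alone, median -0.69, adjusted p = 0.0031). Pluripotency genes had 15 of 26 up and 3 (SFRP2, HESX1 and GAL) down, also when adjusted over the list alone (median 0.43, adjusted p = 4.4e-05), and cholesterol synthesis genes 12 of 19 up and none down (15 and 0 adjusted over the list alone, median 0.47, adjusted p = 2.1e-05). These 6 lists held with an estimated correlation. The fibroblast median was -0.22 without the detection filter, the Nodal median -0.16 with array weights and the pluripotency median 0.65 after background correction. The p53 list did not pass this test (median -0.11, adjusted p = 0.093).

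A further 5 lists passed only with the preset correlation. Stress and amino acid response genes had a median change of -0.67 (adjusted p = 0.00013, and adjusted p = 0.21 with an estimated correlation), and heat shock genes one of 0.23 (adjusted p = 0.0037, and adjusted p = 0.051 with an estimated correlation). G1/S genes had a median change of 0.16 (adjusted p = 0.013, and adjusted p = 0.16 with an estimated correlation). Hypoxia and glycolysis genes had -0.29 (adjusted p = 0.022, and adjusted p = 0.19 with an estimated correlation), a call also lost with array weights (median -0.19). Of the 3 measured mesendoderm markers FGF8 and WNT3 fell, also when adjusted over the list alone (median -0.62, adjusted p = 0.0031, and adjusted p = 0.051 with an estimated correlation), a call also lost without the detection filter (median -0.004) and at a detection limit of 0.05 (-0.13), with medians of -0.41 with an offset of 50 and -1.32 after background correction.

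The CCNB1 differences were next set against the changes under the control vector, using comparisons with no array in common. Across the 11390 genes, the 48 h CCNB1 differences ran against the EV changes from 0 h to 96 h, with Pearson's r of -0.634, Spearman's rho of -0.576 and a slope of -0.32, where genes are not independent replicates. Of the 3340 genes that rose in EV samples, 1271 were lower and 102 higher in CCNB1-labelled samples at 48 h, with a median log2 difference of -0.18 (camera p = 6.6e-28, and p = 3.2e-07 with an estimated correlation). Of the 3380 that fell, 987 were higher and 93 lower, with a median of 0.13 (p = 5.7e-25, and p = 4.8e-06 with an estimated correlation). Genes at the ends of this relation included SPP1 and NTS, which fell in EV samples and were higher in CCNB1-labelled ones, and LMO1, which did the opposite, whereas RAX was below detection in both groups at 48 h.

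Of 4 such relations computed, 2 others were limited by shared arrays or chips. The 96 h CCNB1 differences against EV 48 h minus EV 0 h, which crosses chips, gave r of -0.351. Against EV 96 h minus EV 0 h, which shares the EV 96 h arrays, r was -0.812 where unchanged groups simulated against those arrays gave -0.501, with a covariance of -0.213 against a simulated -0.0047. The fourth, the 96 h on the 48 h CCNB1 differences, shares no arrays and stays within chips, and gave r of 0.439. Of the called genes, 740 were higher at both times where independent lists of those sizes would share 351, and 937 were lower at both where 402 would be shared.

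**Figure D3:**
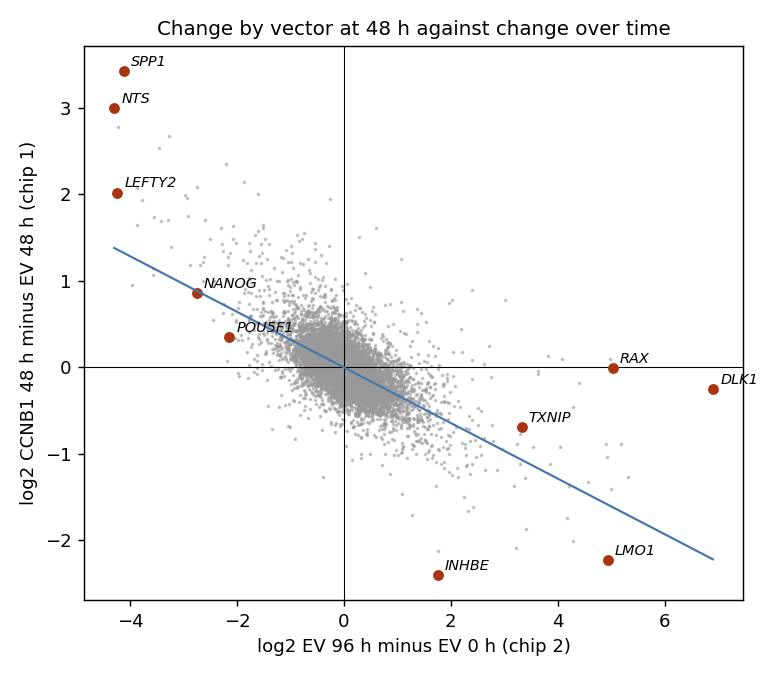
Each point is 1 of 11390 genes, with its log2 EV 96 h minus EV 0 h difference (horizontal axis) and its log2 CCNB1 48 h minus EV 48 h difference (vertical axis), and the least-squares line. The line falls with a slope of -0.32 (r = -0.634), and SPP1 and NTS lie at the upper left.

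Across chips, levels can only be read side by side. POU5F1 averaged 3588, 2324 and 815 in EV samples at 0, 48 and 96 h, and 2957 and 2915 in CCNB1-labelled samples at 48 and 96 h. NANOG averaged 879, 363 and 131 in EV samples and 658 and 385 in CCNB1-labelled samples. SOX2 averaged 5596, 8377 and 10550.5 in EV samples and 7148 and 9129 in CCNB1-labelled samples. The level of SPP1 was 3123, 226 and 181 in EV samples and 2415 and 338 in CCNB1-labelled samples. DLK1 stood at 83.4, 223 and 9990.4 in EV samples and at 188 and 462 in CCNB1-labelled samples. These time courses were not tested because chip and time cannot be told apart across them.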

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

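Of the tests in this part, the splits with the mean CCNB1 difference removed and the 2 tests of signal at background were chosen after the list results were seen. The difference between CCNB1-labelled and EV samples changed between 48 h and 96 h for 2928 genes by a test of the difference itself. Among 100 of the 200 possible splits of the arrays within each time, 3 gave as many genes, the real one included, with 2928 in the real split and 3103 in the highest other, which kept the 96 h labels and so still carries the whole 96 h difference. These splits ask whether there is any CCNB1 difference at either time and decide nothing on its change. After the mean CCNB1 difference of the 2 times was removed from each gene, 1 of the same 100 splits gave as many genes, the real one. It gave 2921 genes against 1108 in the highest other, which kept the 48 h labels, and 410 in the next, so regrouping these arrays did not reach the real count. The mean removed was computed with the real labels, which can favour the real split. Replicates may be technical, so chance differences between cultures or infections are not excluded. For the plain comparisons, 10 splits of 6 arrays are too few for a share under 0.05: 1 of 10 splits gave as many genes at 48 h (3200, highest other 0), 1 of 10 at 96 h (5367, highest other 0) and 1 of 10 for EV 96 h against 0 h (6720, highest other 0). At 96 h, 4 of the 10 splits part all 3 pairs of same-numbered samples, the real one among them, and the other 6 part 1 pair, with 0 genes in the highest other of each kind.

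FGF/ERK and Nodal target genes were higher in CCNB1-labelled samples at 48 h, and their CCNB1 differences were lower at 96 h, by medians of -0.48 and -0.24. Several of these genes, such as LEFTY1 and, in all but 1 array, NODAL, were at background at 96 h in both groups, which could shrink a difference without a change in regulation. The median change was -0.352 over all 26 members and the same over the 20 detected in all 5 groups (bootstrap 95% interval -1.02 to -0.059). Of these 20, 10 were called lower and 2 higher, where 11.5% of all 9527 genes detected in every group were called lower. The intervals given here resample list members and not arrays, so they treat genes as independent and leave out the spread between arrays. For the FGF/ERK targets the tables argue against loss of signal as the whole cause: over the 15 of 16 members detected in all groups, with all 9 called lower among them, the median was -0.532 (interval -1.16 to -0.044; camera p = 2.2e-08 against the other genes detected, and p = 0.0025 with an estimated correlation). For the Nodal targets it stays open, since 5 of 10 members were detected in all groups, with 1 of the 4 called lower among them and a median of -0.209 (interval -0.94 to 0.45). A difference in how the CCNB1 vector acts early and late remains a hypothesis, and the chips that carry the 2 times stay open as a source of unequal, non-additive effects.

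Other lists whose CCNB1 difference changed between the times by the list test, also with an estimated correlation, were pluripotency genes (median change 0.43), neuroectoderm markers (-0.35), fibroblast genes (-0.69) and cholesterol synthesis genes (0.47). Not held were mesendoderm markers (-0.62, adjusted p = 0.051 with an estimated correlation), G1/S genes (0.16, adjusted p = 0.16 with an estimated correlation), stress and amino acid response genes (-0.67, adjusted p = 0.21 with an estimated correlation), heat shock genes (0.23, adjusted p = 0.051 with an estimated correlation) and hypoxia genes (-0.29, adjusted p = 0.19 with an estimated correlation). Genes with a changed difference under the naming rule were RAX (-4.43), DLK1 (-4.24), LHX2 (-3.83), TXNIP (-3.61), ENC1 (-2.98), LEFTY2 (-1.54), LEFTY1 (-1.05) and NODAL (-1.05), and in the other direction CFAP95 (2.59), GADD45G (2.54), CACHD1 (2.47), IDO1 (2.37), PCDH7 (2.36), POU5F1 (1.48), NANOG (0.70) and CCNB1 (0.56). LEFTY2, LEFTY1 and NODAL were undetected in every EV array at 48 h and 96 h, LEFTY1 also in CCNB1-labelled samples at 96 h, and RAX and LHX2 in both groups at 48 h, so the sizes of these 5 changes rest partly on background signal and are not exact. Outside the genes tested, 262 of the 636 detected probes without a gene symbol differed between CCNB1-labelled and EV samples at 96 h.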

How the results depend on the processing

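The alternatives chosen after seeing the data were the deposited values without quantile normalization, quantile normalization within each chip, background correction from the detection p-values, a replicate block for the 96 h samples and the doubt about CCNB1 96 h replicate 3. No called result reversed direction. Requiring a 1.5-fold change left 584 genes at 48 h, 1355 at 96 h, 2373 for EV 96 h against 0 h and 1141 for the change of the CCNB1 difference, a stricter limit by construction, with 323 higher and 261 lower at 48 h and 572 and 783 at 96 h. Median scaling turned the larger share of calls from lower to higher at 48 h (1631 and 1488), to lower at 96 h (2536 and 2756) and to higher for EV (3737 and 2856), and left 1126 upward and 1669 downward changes of the CCNB1 difference. Every other alternative kept these counts within 1.5 times, from 3024 to 4073 at 48 h, 4746 to 6220 at 96 h, 6593 to 7401 for EV and 2617 to 4040 for the change, each highest with array weights. Leaving out 1 array gave 2466 to 3623 genes at 48 h, 4691 to 5414 at 96 h, 6177 to 7027 for EV and 2407 to 3071 for the change. Without CCNB1 96 h replicate 3 the 4 counts were 3623, 5248, 7027 and 3071. The lists past the threshold numbered 8, 10, 10 and 11 in the same order, 4, 4, 5 and 6 with an estimated correlation, 18, 18, 22 and 18 with fry, and 6 to 8, 9 to 11, 10 to 11 and 11 to 12 on leaving out 1 array. The correlation of -0.634 moved to -0.613 without the detection filter and lay between -0.639 and -0.618 on leaving out 1 array. The cause was not tested. The medians of -0.18 and 0.13 ranged from -0.195 to -0.174 and from 0.123 to 0.141 on leaving out 1 array. Over the other alternatives they ranged from -0.234 (background correction) to -0.145 (median scaling) and from 0.108 (offset of 50) to 0.174 (median scaling). Over all alternatives, calls of named genes kept their side of the threshold in 9833 cases and lost it in 127, and list results in 3238 cases, with 31 lost and 59 gained. With the replicate block over all groups the counts were 3213, 5401, 6759 and 2947. With it for the 96 h samples alone they were 3612, 5740, 7027 and 3360. Neither changed a call of a named gene or list. Over all groups, the 30 correlations of same-numbered deviations ran from -0.322 to 0.367, with 8 above 0.1 and 5 below -0.1. The floors of 8 and 16 lay under every signal, so those settings changed nothing. Chip as a block was not fitted, because chip is already encoded in the groups and a fixed block leaves within-chip differences as they are. Signal over background limits the dim genes, whose folds are bounds, and the lists with most members undetected, such as mesendoderm markers with 3 of 14 measured.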

Other observations

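The tests of slower progress and of an interferon response, and the comparison of CCNB1 96 h with EV 0 h, were chosen after the results were seen, and the test of array background before its value was seen. On the same chip, CCNB1-labelled samples at 96 h differed from EV 0 h in 3815 genes, 1941 higher and 1874 lower. Pluripotency genes had a median log2 difference of -0.028 with 9 higher and 9 lower (camera adjusted p = 0.87). Nodal target genes were lower than at 0 h, with a median log2 difference of -0.44 and 6 of 10 members falling, and FGF/ERK target genes were lower by -0.46 with 10 of 16 falling (camera adjusted p = 1.8e-05 each, held with an estimated correlation). Also held with an estimated correlation were cholesterol synthesis genes, 13 of 19 lower (median -0.31, adjusted p = 6.7e-05), neural crest markers, 5 of 9 higher (TFAP2A, DLX5, SOX9, MSX2 and SOX10, median 0.30, adjusted p = 0.00086), and the 4 measured WNT target genes, all higher (TNFRSF19, AXIN2, APCDD1 and LEF1, median 0.40, adjusted p = 0.0028). Trophectoderm and amnion markers had a median of 0.80 with 7 of 9 members higher (adjusted p = 5.7e-05, and adjusted p = 0.080 with an estimated correlation). Neuroectoderm markers had one of 0.34 with 10 of 19 higher and 3 lower (adjusted p = 0.0016, and adjusted p = 0.080 with an estimated correlation). G2 and mitosis genes had 12 of 29 higher and none lower (adjusted p = 0.0037, and adjusted p = 0.27 with an estimated correlation). BMP target genes had 6 of 10 higher and 3 lower (adjusted p = 0.0053, and adjusted p = 0.25 with an estimated correlation). Fibroblast genes had 7 of 12 lower and 3 higher (adjusted p = 0.013, and adjusted p = 0.080 with an estimated correlation). Histone, hypoxia and mesendoderm genes also passed only with the preset correlation. Stress and amino acid response genes were lower than at 0 h, with a median of -0.55, 11 of 18 lower and 2 higher (adjusted p = 5.7e-05, and adjusted p = 0.20 with an estimated correlation), while in EV they rose by 0.83 from 0 h to 96 h (adjusted p = 0.0036, and adjusted p = 0.36 with an estimated correlation). On a scale set by all genes, with EV 0 h near 0 and EV 96 h near 1, CCNB1 96 h samples lay at 0.415 ± 0.020 (SD, n = 3). On the other chip, EV 48 h samples lay at 0.492 ± 0.010 and CCNB1 48 h samples at 0.170 ± 0.022. Positions on the 2 chips can only be read side by side.

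Hypoxia and glycolysis genes split in both vector comparisons rather than moving as a list. At 48 h the vasodilator peptide gene ADM was 2.71-fold higher and the glucose transporter gene SLC2A1 1.55-fold higher in CCNB1-labelled samples, while VEGFA was 1.84-fold lower and the mitophagy gene BNIP3 1.49-fold lower. At 96 h VEGFA was 3.99-fold lower, with 177 ± 6.34 against 706 ± 30.3, and BNIP3 1.64-fold lower. Among NF-kappaB targets the chemokine gene CCL2 was 2.63-fold lower and the superoxide dismutase gene SOD2 higher by 0.59 on the log2 scale at 96 h.

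Higher pluripotency and lower neuroectoderm genes in CCNB1-labelled samples at 96 h may reflect slower progress along the course seen under the empty vector. That hypothesis needs differences at 48 h to run against the EV changes measured on other arrays. Across all genes tested r was -0.634, which is not specific to these 2 lists. At 48 h pluripotency genes had a median of 0.11 (camera adjusted p = 0.12) and neuroectoderm markers one of -0.066 (camera adjusted p = 0.22). Both medians were opposite in sign to the EV changes, but neither list passed the test. Slower progress therefore remains open for these 2 lists. The median of the stress and amino acid response genes above lay outside the range from EV 0 h to EV 96 h. Slower progress alone would not give this if these genes moved steadily in EV samples, which was not tested. Both calls behind it were lost with an estimated correlation (camera adjusted p = 0.20 and 0.36). It therefore does not decide against slower progress. Differences in array background were tested as an alternative. After background correction the median of the pluripotency list minus that of the neuroectoderm list was 1.62. The medians before correction were 0.58 and -0.67. The correction by itself widens differences of dim genes, so a gap that did not shrink cannot decide on background. A part played by background is not excluded. Chip is shared within each comparison and so cannot produce either difference alone. Since the CCNB1 probe at 48 h went against its label, a cause other than the labelled gene stays open and untested.

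Higher p53 target genes in CCNB1-labelled samples at both times were also set against slower progress. Under slower progress alone and a steady course in EV samples, their 96 h level would lie between EV 0 h and EV 96 h. Those differed by a median of -0.036, but the median over the list was 0.32 above EV 0 h (camera adjusted p = 0.00048). A steady course was not tested, since EV 48 h lay on the other chip, so slower progress stays open here. The interferon list was read for a response to the virus, and the higher of its medians at the 2 times was 0.0765 (lowest camera adjusted p = 0.48). Its members went both ways, 5 higher and 1 lower at 48 h and 2 higher and 5 lower at 96 h. Both groups were infected, so a response common to the 2 vectors would cancel in these differences. The list therefore cannot decide on an interferon response. A p53 response linked to CCNB1 or to its vector is a hypothesis that these tests leave open, with differences in infection or in vector dose untested.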
